A study of Homo sapiens with 2 samples.

How the data were processed

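Gene expression was measured on 2 two-colour microarrays, 1 for each of 2 lung squamous cell carcinoma lines, EBC-1 and SK-MES-1. Per the labels, the Cy5 channel of each array held RNA of cells transfected with the siRNA si-HELLS-3, and the Cy3 channel held RNA of mock cells of the same line, whose transfection field reads that none was done. The labels also call these cells mock and their protocol speaks of microRNA transfection, so whether they received transfection reagent is not settled; no control siRNA is recorded for them. The dye orientation was the same on both arrays, no array was replicated and no dyes were swapped.

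Per the file headers, the arrays (design 072363, made on build hg19) were read with Feature Extraction 12.1.1.1. The deposited scanner files hold the intensity of each spot and of its local background, the software's processed intensity after background subtraction, detrending and dye normalization (linear and lowess), and a log10 ratio of Cy5 over Cy3 with its error. They also give a p-value for each log10 ratio, per the file headers, which comes from an error model within the array and was not used as a test. The table deposited by the authors with the series holds log2 values. Set against the scanner files, these equalled the log2 ratio of the processed signals, Cy5 over Cy3, within 0.01 for 99.97% of the 58201 probes of each array. Their medians were -0.15 for EBC-1 and -0.10 for SK-MES-1, so they had not been centred further.

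Here the median spot signals and median local backgrounds were corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 (R 4.3.3). The design had named mean spot signals; the files used here give median signals, which took their place. Control spots and spots marked as non-uniform or as population outliers (120 spots for EBC-1 and 91 for SK-MES-1) had weight 0 in the loess and were left out afterwards. No gene spot was saturated. Replicate spots of a probe were averaged, and probes well above background in at least 1 channel of the array were kept. Probes of a gene were then averaged with equal weight. The offset of 50 is close to the background-subtracted signal of the typical measured probe (medians of 60.6 for Cy3 and 97.8 for Cy5 on the EBC-1 array, and 59.2 and 124.1 on the SK-MES-1 array). It pulls ratios of dim genes towards 0, so folds of such genes are understated.

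The files name probes by accession. Of 25297 curated transcript accessions, 24726 matched a symbol in a RefSeq gene table of assembly GRCh38.p14, compared without version numbers; other probes kept the file's name. Because the array was designed on another build, the table gave names only and no coordinates are reported. Of 563 genes in 27 gene lists fixed before the data were examined, 547 had a probe.

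With 1 array per line, sizes are given without a p-value, and genes at least 2-fold higher or lower (absolute log2 ratio of 1 or more) were counted. The error given beside a gene is the software's own error of its log ratio within the array, not a spread between cultures. The median of a gene list was placed among 10000 random lists of the same size, matched on mean log2 intensity in 20 bins, and was called outside percentiles 2.5 to 97.5; a list needed at least 3 measured genes. This describes the array and is not a test over samples. Overlaps between lines were set beside the number expected for independent lists. The 2 lines were also taken as 2 samples of the knockdown in limma (lmFit and eBayes, intercept against 0, Benjamini-Hochberg at 0.05), with 1 residual degree of freedom plus the prior. The labels do not say whether the lines were handled on separate days, and both arrays came from 1 slide and 1 scan, so slide and scan could not differ between lines. For a gene above background in 1 channel only, the fold is a lower bound, the bright channel over the higher of the dim channel's own value and the lowest signal well above background on that array. These bounds were taken per channel after loess and Aquantile and stay open to dye bias.

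Named genes followed a rule fixed before the data were examined. They are HELLS; per line the 10 highest and 10 lowest genes above background in both channels whose probes all had the same sign; up to 3 genes per line and direction with the largest lower bound; the 10 highest and 10 lowest over both lines by the smaller absolute log2 ratio; the 5 genes on each side with the largest difference between lines, both of these sets from genes above background in both channels of both arrays with probes of the same sign; and up to 4 members per list with the largest absolute mean. Not every gene chosen by this rule is printed. Genes named outside this rule are marked as such.

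The list step and the limma step were tested on simulated data made from the 22862 genes measured in both lines. The limma step called 78 of 100 genes changed 2-fold and 98 of 100 changed 4-fold in both lines, with 1 false call. For this step the noise was drawn independently for each line from genes of like intensity, and the planted change was the same in both. Variance particular to a gene and bias common to both arrays were thus left out. The shares called by limma therefore need not hold for the real arrays. The list step called 100 of 100 lists of 20 genes shifted by 0.30 on the log2 scale, and 4 of 100 lists without a shift.

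The alternatives were the software's processed log ratio, no background correction, an offset of 10, median centring in place of loess, probes above background in both channels, no filter on dim probes, the brightest probe of a gene, outlier spots kept, the values of the deposited series table, thresholds of 1.5-fold and 3-fold, eBayes with trend, eBayes robust, random lists without intensity matching, and quantile normalization of the Cy3 channel for mock levels. A shift of the processed log ratio to the spike-ins of each array and the comparison of list medians between the lines were added after the data were seen. The shift assumes that the spike-ins were added to the channels in the intended proportion, which no label states. The series table nearly repeats the processed log ratio, and the shift adds a constant to it. Counts of alternatives for list calls thus hold this ranking more than once and are not separate checks. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.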

Results

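The study asked which genes change when HELLS, an SNF2-family chromatin remodelling helicase, is silenced in lung squamous cell carcinoma. EBC-1 and SK-MES-1, established human lines of this cancer, were transfected with the siRNA si-HELLS-3 and compared with mock cells of the same line on 1 two-colour array each. There were thus 2 comparisons with 1 array apiece and no replicate, and this number limits the precision of every value. In EBC-1, 52.5% of the gene spots lay well above background in at least 1 channel, which gave 24024 measured genes. In SK-MES-1 the share was 59.6%, with 27519 genes. More spots lay above background in Cy5, the si-HELLS-3 channel, than in Cy3, the mock channel, with 52.3% against 43.4% in EBC-1 and 59.5% against 47.7% in SK-MES-1; dye and sample cannot be told apart here. Log2 ratios of repeated spots of 1 probe had a median SD of 0.047 in EBC-1 and 0.045 in SK-MES-1, probes of the same gene a median SD of 0.097 in EBC-1 and 0.085 in SK-MES-1, and the software's error of a log2 ratio had a median of 0.21 on both.

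HELLS, the target of the siRNA, was lower in the transfected cells of both lines. In EBC-1 its log2 ratio was -1.62, a 3.06-fold decrease to 32.6% of mock, as the mean of 2 probes (SD between probes 0.41). Probe A_23_P12816 gave -1.90 and probe A_33_P3258117 gave -1.33. In SK-MES-1 the log2 ratio was -1.03, a 2.04-fold decrease to 49.1% of mock (SD between probes 0.23), with -1.19 and -0.86 for the same probes. The software's error was 0.26 to 0.33 for these values. The processed log ratio, which has no offset, gave larger decreases of 5.39-fold in EBC-1 and 3.62-fold in SK-MES-1. In EBC-1, 12 genes had a lower ratio than HELLS, and in SK-MES-1 58 genes did; by the processed log ratio 28 and 23 genes did.

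In EBC-1, genes of DNA replication were lower in si-HELLS-3 cells and genes of squamous differentiation, inflammation and extracellular matrix were higher. Of 32 genes of DNA replication and G1/S, all had a log2 ratio below 0, the median was -0.82, and 9 were at least 2-fold lower. They included RRM2, a subunit of ribonucleotide reductase, 2.73-fold lower, MCM6 of the replicative helicase and its partner CDC45, both 2.60-fold lower, and TYMS, thymidylate synthase, 2.44-fold lower. All 14 measured replication-dependent histone genes were below 0 (median -0.89), and 7 were at least 2-fold lower, among them H1-5 (2.34-fold), H1-4 (2.31-fold) and H4C2 (2.25-fold). Of 29 genes of G2/M and mitosis, 28 were below 0 (median -0.52), but none reached 2-fold, with CENPA, the centromeric histone, at -0.92, UBE2C at -0.88 and BUB1B at -0.87. Homologous recombination genes had a median of -0.27, with BARD1 at -0.76 and FANCI at -0.67. Each of these 4 medians lay below all 10000 random lists of like intensity. Their size depended on the processing. The median of DNA replication genes was -1.12 with 21 members at least 2-fold lower by the processed log ratio, and -0.35 with 1 member after median centring. Histone genes had 8 and 0 such members under these settings, and G2/M genes 5 and 0, with G2/M medians of -0.71 and -0.11.

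Of 16 measured squamous terminal differentiation genes in EBC-1, 14 were above 0 (median 0.31) and 6 were at least 2-fold higher. The median was 1.17 by the processed log ratio, 1.09 over 12 genes above background in both channels and 0.17 over 21 genes without the filter on dim probes, and the list was called under each. SERPINB3 was 4.47-fold higher, S100A8, a calcium-binding protein of inflamed epithelium, 3.57-fold, and SPRR1A, a cornified envelope precursor, 2.57-fold. Probes for SERPINB3 can also capture the near-identical SERPINB4. Squamous lineage genes had a median of 0.33 over 11 measured members, and of 0.04 over all 22 without the filter; SOX2, a transcription factor of squamous cancers, was 3.75-fold higher, PERP stood at 0.65 and JUP at 0.60, while TP63, dim on this array, stood at -0.06. Genes of mesenchyme and matrix had a median of 0.36 (3 of 17 at least 2-fold higher), with SNAI1, a repressor of epithelial genes, 2.65-fold higher and TGFBI 2.10-fold higher. Leaving dim probes unfiltered ended this call. In SK-MES-1 the median of this list was 0.08 at percentile 87.6. However, 8 of 11 alternatives called it higher there, the processed log ratio among them (percentile 99.4). The median difference per gene, EBC-1 minus SK-MES-1, was 0.23, above all random lists. NF-kB and cytokine genes had a median of 0.28, with IL6 3.06-fold higher, CCL2 at 0.89, CXCL1 at 0.80 and NFKBIA at 0.68. They were not particular to EBC-1: in SK-MES-1 their median was 0.11 at percentile 96.97, with 2 members at least 2-fold higher. There 7 of 11 alternatives left the list uncalled and the others called it higher. The median difference per gene, EBC-1 minus SK-MES-1, was -0.02, inside the random range. Epithelial junction genes had a median of -0.16, which turned positive under median centring and under the shift to the spike-ins. Relative to genes of like intensity the list stayed called lower in 11 of 11 alternatives. CLDN1 was 2.58-fold lower and TJP1, another junction gene, stood at 0.81. Markers of leukocytes, endothelium and fibroblasts had a median of 0.09, percentile 99.1, with HLA-DRA 2.40-fold higher, CD74 at 0.52, CD14 at 0.09 and TYROBP at 0.03; 3 of 11 alternatives ended this call. p53 targets had a median of 0.12 at percentile 98.1, with GDF15, a stress-induced cytokine, 4.41-fold higher and SULF2 3.48-fold higher, but PLK3 at -0.63; 8 of 11 alternatives ended this call, the processed log ratio among them (percentile 93.3).

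The highest genes of EBC-1 besides these were DEFB1, a beta-defensin (4.76-fold, log2 error 0.44), HEG1 (3.97-fold), MGP, a matrix protein (3.96-fold), SAA2, an acute-phase protein with a near-identical copy (3.79-fold), SPEF1 (3.55-fold) and P2RY6, a nucleotide receptor (3.54-fold). The lowest were PSMA2, a proteasome subunit (6.10-fold, log2 error 0.33), GCSH of the glycine cleavage system (6.09-fold), OIP5, a centromere factor (5.47-fold), MAL2 (4.67-fold), PRNP, the prion protein (3.60-fold), UBR7 (3.51-fold), TFRC, the transferrin receptor (3.44-fold), ENOPH1 (3.43-fold), NAA50 (3.35-fold) and GNG10 (3.22-fold). In all, 131 genes were at least 2-fold higher and 130 at least 2-fold lower, 1.09% of those measured. Higher genes made up 50.2% of these calls, 69.4% of 2241 calls by the processed log ratio, 96.5% of 822 calls after median centring and 96.1% of 4831 calls after the shift to the spike-ins, so the balance depends on the processing. Of genes above background in 1 channel only, S100P was at least 1.76-fold higher, DYNLRB2 at least 1.69-fold and ID4 at least 1.68-fold higher, and CYP4F30P at least 2.40-fold lower.

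In SK-MES-1, genes of DNA replication and histones were again lower, genes of the integrated stress response were lower, and interferon-response genes were higher. Of 32 DNA replication genes 31 were below 0 (median -0.36) and all 14 histone genes were (median -0.52), with no member at 2-fold; both medians turned positive under median centring and the spike-in shift, while staying below all random lists. CDC45 stood at -0.84, RRM2 at -0.61, MCM6 at -0.56 and TYMS at -0.48, and among histones H1-4 stood at -0.80 and H4C8 at -0.72. The 29 G2/M and mitosis genes had a median of 0.02, inside the random range (percentile 39.5), with BUB1B at -0.43 and CENPA at -0.14. Of 20 genes of the unfolded protein and integrated stress response 16 were below 0 (median -0.41, turning positive under the same 2 settings) and 5 were at least 2-fold lower. By the processed log ratio 8 were, and after median centring none. The 5 included ASNS, asparagine synthetase (2.66-fold), TRIB3 (2.43-fold) and PSAT1 of serine synthesis (2.01-fold), with PHGDH of the same pathway at -0.92. Hypoxia and glycolysis genes had a median of -0.25, also positive under those settings, with TPI1 at -0.51 and ENO1 at -0.36, while ADM stood at 0.84. The stress response list and the hypoxia list each stayed called lower in 11 of 11 alternatives.

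Of 24 measured type I interferon response genes in SK-MES-1, 22 were above 0, and the median of 0.35 lay above all random lists (0.62 by the processed log ratio and 1.06 after median centring, also above all). OASL was 2.32-fold and IFIT2 2.28-fold higher, IFIT3 stood at 0.98 and IFI44L at 0.90. Cholesterol synthesis genes had a median of 0.21 (17 of 20 above 0), with HMGCS1 at 0.88 and SQLE at 0.59, but IDI1 at -0.78. Clustered protocadherins had a median of 0.11 (percentile 98.9, PCDHB2 at 0.30 and PCDHB13 at 0.27), a call that median centring ended. Germline and cancer-testis genes had a median of -0.13 (percentile 0.450) over 11 measured members, with MAGEA6 at -0.14 and STK31 at 0.28. That median turned positive under median centring and the spike-in shift, and the call ended under these, under the processed log ratio (percentile 3.31), under the series table and without the filter on dim probes.

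The highest genes of SK-MES-1 were TNFSF10, a death receptor ligand (3.50-fold, log2 error 0.29), PTGIS, prostacyclin synthase (3.43-fold), CLDN11 (3.28-fold), BAMBI, a decoy receptor of the TGF-beta family (2.95-fold), DPCD (2.87-fold), VCAN, a matrix proteoglycan (2.77-fold), UGCG (2.64-fold), NDRG4 (2.63-fold), ADAMTS10 (2.62-fold) and RARRES1 (2.53-fold). The lowest were SLC7A5, an amino acid transporter (4.01-fold, log2 error 0.30), PSMA2 (3.49-fold), TFRC (3.44-fold), PRNP (3.29-fold), OIP5 (3.22-fold), GCSH (2.98-fold) and ABRACL (2.77-fold). SNAR-F (2.70-fold) and SNAR-H (2.60-fold) were also among them but belong to a family of near-identical copies and are uncertain. In all, 51 genes were at least 2-fold higher and 66 at least 2-fold lower, 0.425% of those measured. Higher genes made up 43.6% of these calls, 80.8% of 1846 calls by the processed log ratio, 99.9% of 1763 calls after median centring and 99.8% of 10703 calls after the shift to the spike-ins. Among genes above background in 1 channel only, no bound reached 2-fold; the largest were TMT1A, at least 1.45-fold higher, and GJB5, at least 1.28-fold lower.

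Both lines shared a set of strongly lowered genes. Of 22862 genes measured in both, 28 were at least 2-fold lower in each line, where 0.36 would be expected for independent lists, and 16 were at least 2-fold higher, where 0.25 would be expected. No gene was at least 2-fold in opposite directions (0.605 expected); the processed log ratio gave 7, with 33.5 expected. PSMA2, TFRC, PRNP, OIP5 and GCSH led the lower genes, followed by ABRACL, NT5E, an ectonucleotidase (-1.42 in EBC-1 and -1.32 in SK-MES-1), SLC31A2, a copper transporter (-1.39 and -1.28), SMN1 of the snRNP assembly complex (-1.66 and -1.25), which is uncertain because its near-identical copy SMN2 stood at -0.27 and -0.17 by its own probe, and NAA50 (-1.74 and -1.23). MCL1, a survival factor of the BCL2 family, was 2.13-fold lower in EBC-1 and 2.08-fold lower in SK-MES-1, and the imprinted gene PHLDA2 was 2.39-fold and 2.03-fold lower. The higher genes were led by NDRG4 (1.32 in EBC-1 and 1.40 in SK-MES-1), HEG1 (1.99 and 1.32), KITLG, the ligand of the KIT receptor (1.52 and 1.32), DNAAF4, a dynein assembly factor (1.34 and 1.27), PLPP3 (1.24 and 1.25), TGFBR2, a TGF-beta receptor (1.47 and 1.21), IFIT2 (1.18 and 1.19), OSCP1 (2.15-fold and 2.29-fold) and PIERCE1 (1.24 and 1.14). Probes disagreed in size for MAL2, where 1 of 2 probes stood at -0.53 in EBC-1 and at 0.00 in SK-MES-1. They also did for NAA50, where 1 of 2 stood at -0.67 and -0.48, for NT5E (-0.85 and -0.63) and for IFIT2 (0.70 and 0.70). The shared 2-fold calls of these 4 genes thus rest on 1 probe each. PSMA2, TFRC, PRNP, OIP5, GCSH, ABRACL, SLC31A2, SMN1, NDRG4, HEG1, KITLG, DNAAF4, PLPP3 and TGFBR2 had only 1 measured probe each, so no second probe checks them.

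**Figure D1:**
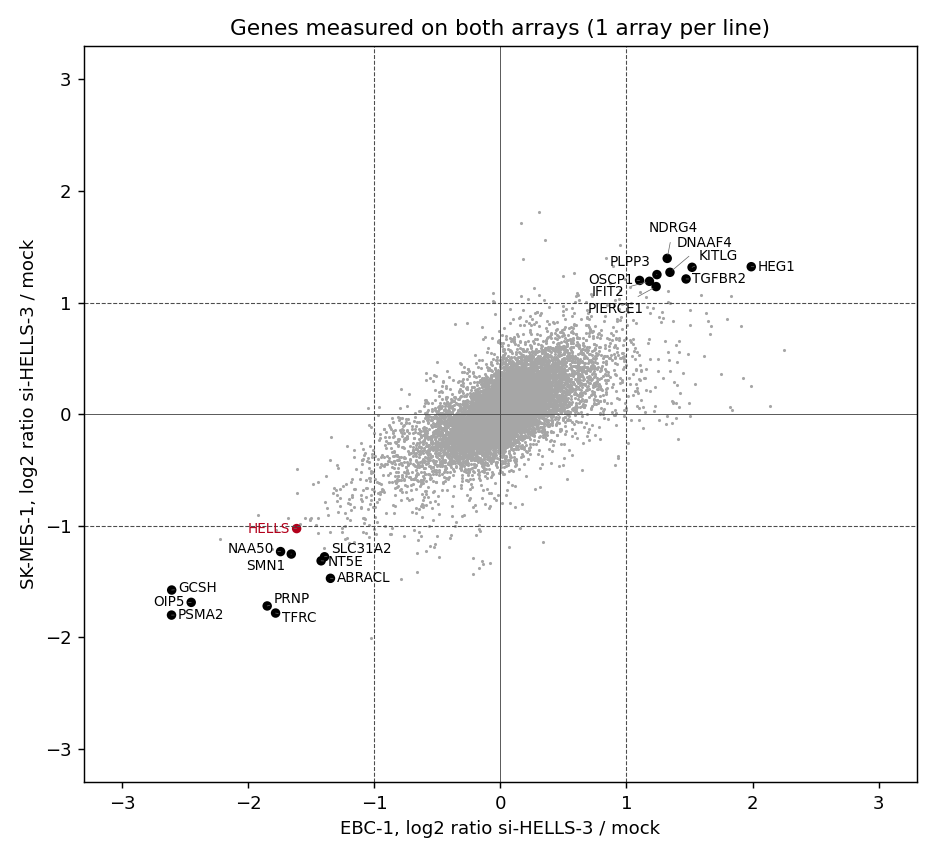
Each grey point is 1 of the 22862 genes measured on both arrays, with its log2 ratio of si-HELLS-3 over mock in EBC-1 (x axis) and in SK-MES-1 (y axis); dashed lines mark 2-fold. HELLS (red) lies at -1.62 and -1.03, the named shared genes (black) lie in the upper right and lower left corners, and no point lies in the upper left or lower right corner.

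Across genes, the log2 ratios of the lines correlated with a Pearson r of 0.66 and a Spearman rho of 0.57; genes are not independent replicates, and a dye bias of single genes would be common to both arrays. Taking the lines as 2 samples, limma called 0 of 22862 genes at an adjusted p of 0.05 (smallest adjusted p 0.094, HELLS 0.096), while 4947 genes had an unadjusted p under 0.05, where 1143 would be expected by chance. With a trend in the variance prior, limma called 254 genes higher and 230 lower, HELLS among them (adjusted p 0.038). Within the lists, 23 of the 32 DNA replication genes and 12 of the 14 histone genes were lower at 0.05 in limma when adjusted over the list alone, against 0 when adjusted over all genes. HELLS, a list of its own, also passed alone. Each of the other lists had at most 5 genes passing in either direction when adjusted over the list alone.

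The lists fixed for the known surroundings of HELLS were called in neither line, except germline and protocadherin genes in SK-MES-1. DNA methylation machinery genes had a median of -0.08 in EBC-1 (percentile 2.65) and -0.01 in SK-MES-1, both inside the random range and both turning positive under median centring and the spike-in shift; in EBC-1, 2 of 11 alternatives called the list lower. CDCA7, the partner of HELLS in nucleosome remodelling, stood at -1.04 in EBC-1 and -0.48 in SK-MES-1, UHRF1 at -0.86 and -0.37, DNMT1 at -0.48 and -0.12, and DNMT3A at 0.34 and 0.29. Other remodelling helicases and cofactors were inside the random range, but in SK-MES-1 close to its upper end (percentile 96.9), and 5 of 11 alternatives called them higher there, the processed log ratio among them (percentile 97.7), with CHD7 at 0.87 and 0.64 and SMARCA1 at 0.58 and 0.80. Imprinted genes were inside it as well, with CDKN1C at 0.49 and 0.93 and NDN at 0.92 and 0.35. Of the 28 germline genes 5 were measured in EBC-1 and 11 in SK-MES-1.

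**Figure D2:**
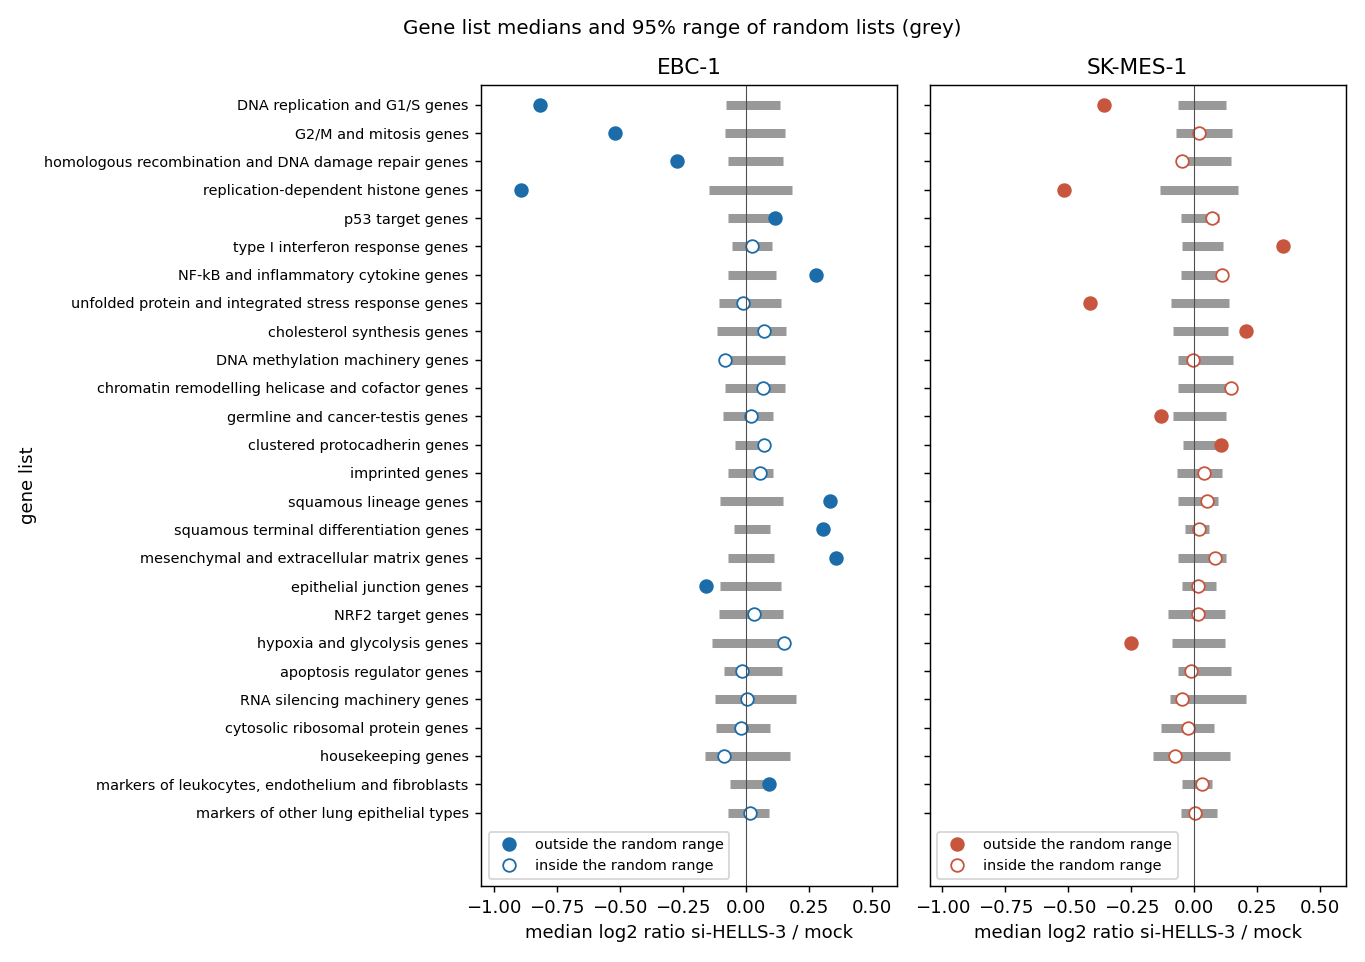
Median log2 ratio of si-HELLS-3 over mock of each gene list (circles) in EBC-1 (left) and SK-MES-1 (right), with the central range of 10000 random lists of like intensity that was used for calls in grey; filled circles lie outside it. DNA replication and histone genes lie below the range in both lines, and interferon genes lie above it in SK-MES-1 only.

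Of 26 lists with a test, 11 were called in EBC-1 and 8 in SK-MES-1, and no list was called in opposite directions. For lists of genes drawn singly, 1.30 calls would be expected in each line. Members of a list can vary together and some genes are in more than 1 list, so the excess over 1.30 is not a test. Opposite calls did appear under alternatives: hypoxia genes were called higher in EBC-1 (percentile 97.9) and lower in SK-MES-1 (percentile 0) by the processed log ratio, and likewise by the series table, the spike-in shift and random lists without intensity matching. Interferon genes were called lower in EBC-1 (percentile 0.820) and higher in SK-MES-1 (percentile 100) after median centring. Lists that lay inside the random range in both lines covered NRF2 targets (with AKR1B10 2.83-fold higher in EBC-1 and 1.91-fold higher in SK-MES-1), apoptosis regulators, RNA silencing machinery (TNRC6A at 0.90 and 0.98), ribosomal proteins, housekeeping genes and markers of other lung epithelial types, besides those above. Of these, apoptosis regulators were called lower in SK-MES-1 by 3 of 11 alternatives, the processed log ratio among them (percentile 2.02), RNA silencing genes higher in EBC-1 with the brightest probe, and housekeeping genes lower in both lines without intensity matching. The control genes GAPDH and ACTB stood at -0.06 and -0.14 in EBC-1 and at -0.19 and 0.01 in SK-MES-1. Median centring in place of loess raised the median of all genes by 0.15 in EBC-1 and by 0.25 in SK-MES-1, and the spike-in shift raised it by 0.55 and 0.87; list statements are relative to genes of like intensity.

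The response of several lists differed in size between the lines. This is described here by the median difference of EBC-1 minus SK-MES-1 per gene and its percentile among random lists. With 1 array per line the difference has no test. HELLS itself was at 32.6% of mock in EBC-1 and at 49.1% in SK-MES-1, with software errors of 0.30 and 0.27 on the log2 scale. The lines may therefore not be compared at equal silencing. G2/M genes differed by -0.65 and DNA replication genes by -0.52, both below all random lists, and interferon genes differed by -0.33. Stress response genes differed by 0.54, hypoxia genes by 0.39 and squamous lineage genes by 0.27. Of single genes well above background in both channels of both arrays and with all probes of the same sign, GDF15 (2.14 in EBC-1 and 0.07 in SK-MES-1), DEFB1 (2.25 and 0.57), LOX (1.41 and -0.23), SPRR2E (2.84-fold higher and -0.02; close in sequence to other SPRR2 genes and uncertain) and AREG, an EGF receptor ligand (0.34 and -1.15), lay furthest above in EBC-1. TNFSF10 (0.31 and 1.81), BAMBI (0.35 and 1.56), ADAMTS10 (0.18 and 1.39), SCARNA13 (-0.36 and 0.81) and MEGF6 (-0.06 and 1.08) lay furthest below. Outside that filter, CLDN11 (0.16 and 1.71) lay further below. S100A8 (1.84 and 0.04), P2RY6 (1.82 and 0.07), MGP and SAA2, also outside it, lay as far above as the genes named first. By the processed log ratio CLDN11 stood at 2.82 in EBC-1 and 1.76 in SK-MES-1, which turns its difference. SAA2 stood at 2.72 and 2.45, so most of its difference depends on the processing. S100A8, P2RY6 and MGP kept a clearly higher ratio in EBC-1 there.

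**Figure D3:**
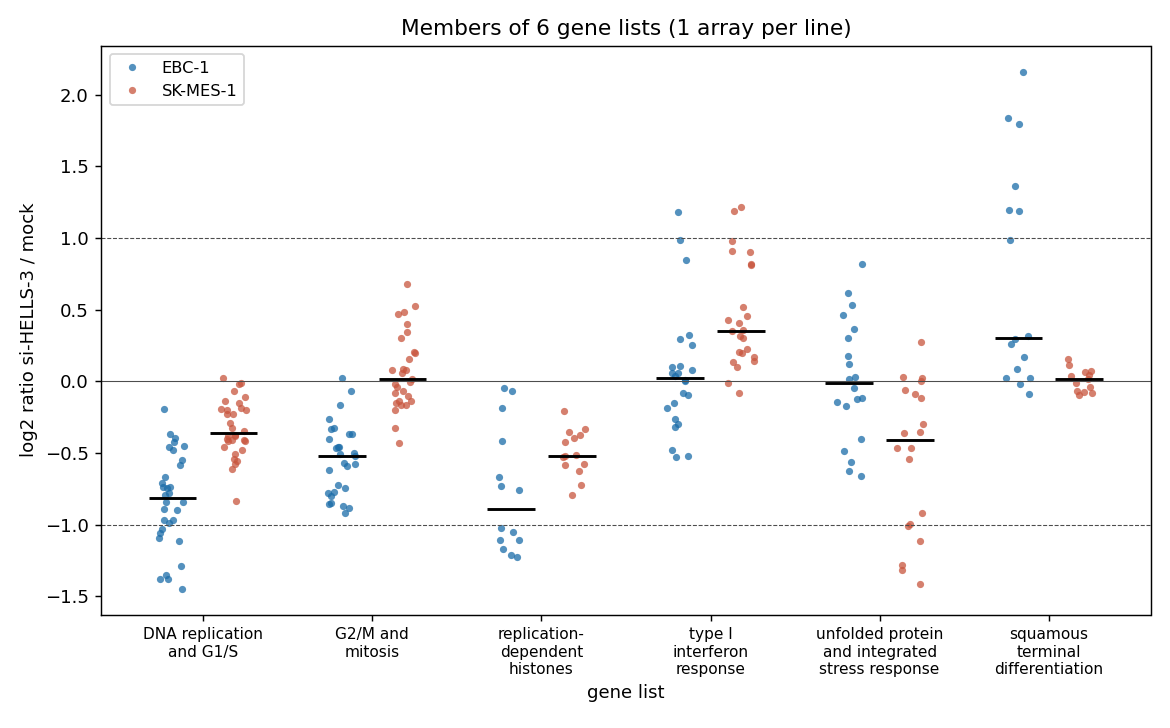
Log2 ratio of si-HELLS-3 over mock of each measured member of 6 gene lists (points) in EBC-1 (blue) and SK-MES-1 (red), with the list median as a black bar and 2-fold as dashed lines. The median of G2/M genes is -0.52 in EBC-1 and 0.02 in SK-MES-1, and that of interferon genes 0.02 and 0.35.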

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

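Of the tests below, those of off-target silencing, of dye bias of whole transcripts, of normalization, of cycling cells and of transfected RNA were chosen after the result was seen. No list was called in opposite directions in the lines and no named gene was at least 2-fold in opposite directions, but hypoxia genes were called in opposite directions under 4 alternatives and interferon genes after median centring. The spike-in RNAs, used above only for the added alternative, did not lie where the software's dye normalization would put them: their fit had an intercept of -0.52 on the log2 scale on the EBC-1 array and -0.85 on the SK-MES-1 array, with no control array to set against them. These values, and every result of the spike-in shift, assume that the spike-ins were added to the channels in the intended proportion, which no label states. The slope of observed against expected log ratios was 0.81 on the EBC-1 array and 0.80 on the SK-MES-1 array, so spike-in ratios were compressed.

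Of the genes at least 2-fold lower in both lines, 10, led by PSMA2, GCSH and OIP5, were lower than HELLS in both, but the offset compresses the ratio of HELLS. By the processed log ratio 6 genes were lower than HELLS in both, and of the first 10 only OIP5 was among them. For genes with more than 1 probe, bias or cross-hybridisation of single probes is argued against as the whole cause. There, 16 probes at least 2-fold lower on both arrays had other probes of the same gene. All 16 sets of other probes were below 0, with a median of -0.61 against -1.37 for the selected probes. Part of the size may still be specific to a probe, given that gap. HELLS is among the 16, DUS1L entered with each of its probes, and some of these genes were less than 2-fold lower as a mean of probes. PSMA2, GCSH, OIP5, PRNP and TFRC had only 1 probe each, so for them this test cannot tell. Off-target silencing cannot be told apart from an effect of HELLS, because only 1 siRNA was used and its sequence is not given in the sources used here. A dye bias of whole transcripts also stays open, since both arrays had the same orientation and correlated at 0.66 across genes.

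Genes of DNA replication were lower than genes of like intensity in both lines. The highest percentile of the list over both lines and all alternatives was 0, so the low percentile did not depend on the background step. Random lists were matched on intensity, so a normalization that differs by intensity alone could hardly move the percentile. The alternatives in normalization thus cannot exclude it as a cause. The spike-in shift moves every gene of an array alike, so it could not have changed the percentile. The list median of SK-MES-1 did change, from -0.36 to 0.29 with median centring and to 0.35 with the spike-in shift. A level below mock in that line therefore depends on the processing. With median centring the median of all SK-MES-1 genes was 0.26, so the list lay no lower than the typical gene there. In EBC-1 the list then stood at -0.35 beside 0.17 for all genes. Fewer cycling cells would lower G2/M genes too. In EBC-1 their median of -0.52 (bootstrap interval over genes -0.72 to -0.46) was below -0.41, which is 0.5 of the replication median, as this explanation predicts. After median centring it was -0.11 beside a replication median of -0.35 and no longer reached that share. That setting raised the median of all EBC-1 genes by 0.15, which by itself moves such a share. The loss of the share there thus does not decide, and fewer cycling cells in EBC-1 stay open. In SK-MES-1 the G2/M median of 0.017 (-0.08 to 0.16) lay above the corresponding -0.18, which argues against fewer cycling cells as the cause there. A lower rate of DNA replication after loss of HELLS, or an arrest within the cycle, stays open as a hypothesis, as does an effect of transfection, since no control siRNA is recorded for the mock cells.

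Interferon genes were higher in SK-MES-1 and centred near 0 in EBC-1, where median centring called them lower than genes of like intensity (percentile 0.820). Signals too dim to measure in EBC-1 are argued against: among 21 interferon genes above background in both channels of both arrays, SK-MES-1 exceeded EBC-1 in 21, with a median difference of 0.35 (quartiles 0.23 and 0.58). A response of SK-MES-1 to transfected RNA itself (list median 0.35) cannot be told apart from a response to the loss of HELLS, because no control siRNA is recorded for the mock.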

How the results depend on the processing

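No paired analysis was possible because each line has 1 array and the labels carry no replicate numbers; leaving out a line would leave limma no residual degrees of freedom. Of the values below, those for the shift to the spike-ins were chosen after the data were seen. Signals were low against background, so the offset and the background step set the size of ratios of dim genes, and no call was made between cultures. The counts for EBC-1, SK-MES-1 and both lines in the same direction (261, 117 and 44) became 1126, 648 and 334 at 1.5-fold and 35, 8 and 4 at 3-fold. They became 2241, 1846 and 409 with the processed log ratio, 2245, 1846 and 409 with the series table, 486, 221 and 99 without background correction, 558, 252 and 112 with an offset of 10, 822, 1763 and 521 with median centring, and 4831, 10703 and 2732 with the spike-in shift. Opposite directions held 0 genes, against 7, 8 and 13 with the processed log ratio, the series table and the spike-in shift.

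The correlation of 0.66 became 0.51 with the processed log ratio, the series table and the spike-in shift, 0.64 without background correction, 0.62 with an offset of 10, 0.73 with median centring, 0.68 for probes above background in both channels and 0.62 without the filter. The limma count of 0 became 484 with trend, 1096 without background correction, 1434 with an offset of 10, 6451 with median centring and 13180 with the spike-in shift. HELLS (-1.62 in EBC-1 and -1.03 in SK-MES-1) stood at -2.43 and -1.85 with the processed log ratio and the series table, -2.08 and -1.44 without background correction, -2.17 and -1.52 with an offset of 10, and -1.25 and -0.58 with median centring. The number of lists called in SK-MES-1 was 8, and 13 without intensity matching; mesenchymal genes, not called there, were called in 8 of 11 alternatives.

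Of 572 values of list medians under the alternatives, 12 turned the sign of a called list and are counted apart. All of these except the values of germline genes kept their call. Of the others, 510 kept the call, 16 lost it and 34 gained one. Those 12 were the median of epithelial junction genes in EBC-1, 0.24 with median centring and 0.31 with the spike-in shift, and in SK-MES-1 those of DNA replication genes (0.29 and 0.35), histone genes (0.27 and 0.28), stress response genes (0.16 and 0.40), germline genes (0.38 and 0.66) and hypoxia genes (0.50 and 0.50). Both settings raise the median of all genes, which is built into the spike-in shift; for median centring the cause was not tested. For the other values named here the cause was not tested either, except that a lower or higher threshold gives more or fewer genes by construction. Of 976 values of named genes, 631 stayed within the software's error, 345 moved further and none of those at least 2-fold turned sign.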

Other observations

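The ciliary list below and its test were chosen after the named genes were seen. The mock channels show how the lines differ before silencing, as a description with 1 array each. SK-MES-1 held more mesenchymal and cancer-testis transcripts, and EBC-1 more epithelial and some inflammatory ones. CTAG2 was at least 68.3-fold and MAGEA6 at least 44.7-fold higher in SK-MES-1, where EBC-1 was not well above background; MAGEA family members are close in sequence and are uncertain as single genes. COL1A1, a fibrillar collagen, was 18.2-fold and VIM, the intermediate filament of mesenchyme, 5.45-fold higher in SK-MES-1, and S100A2 was 25.3-fold higher. In EBC-1 the adherens junction gene CDH1 was at least 47.1-fold higher, CLDN7 18.5-fold, EPCAM 13.8-fold and ESRP2, an epithelial splicing factor, 11.9-fold. The chemokine genes CXCL3 and CXCL2 were 18.5-fold and 9.97-fold higher in EBC-1. Of 18 NF-kB and cytokine genes compared, 5 were at least 4-fold higher in EBC-1 and 0 in SK-MES-1. Their median log2 difference was 0.49, but CCL2 was 2.91-fold and ICAM1 2.03-fold higher in SK-MES-1. Mock HELLS was 2.01-fold higher in EBC-1 than in SK-MES-1. In all, 164 genes were at least 4-fold higher in EBC-1 and 276 in SK-MES-1, of 22719 compared. These genes were chosen from the lists after their values were seen.

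Several genes among those highest in both lines act in cilia (DNAAF4, PIERCE1, OSCP1 and, in EBC-1, SPEF1). A list of 74 other ciliary genes was therefore written, leaving these out, and placed among random lists of like intensity. In EBC-1 49 of 61 measured members were above 0 with a median of 0.13, and in SK-MES-1 60 of 63 with a median of 0.25. The lower of the percentiles of the lines was 100, and the percentile was 100 under every processing alternative in both lines. IFT172, a subunit of the intraflagellar transport complex, stood at 0.94 in EBC-1 and 0.68 in SK-MES-1, TCTN1 of the ciliary transition zone at 0.70 and 0.73, and KIF3B of the anterograde motor at 0.53 and 0.67, while TUBB4B stood at -0.61 and -0.24. A raised ciliary programme in si-HELLS-3 cells is a hypothesis from these arrays; it may equally follow from transfection, which a mock without a recorded control siRNA does not separate, and cilia themselves were not measured.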
